A study of Mus musculus with 10 samples.

How the data were processed

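RNA from mammary glands of BALB/c mice was sequenced in 10 libraries, 5 from glands injected with lipopolysaccharide (LPS) and 5 from glands injected with phosphate-buffered saline (PBS). Per the labels, glands were frozen, total RNA was isolated with a column kit, and libraries were made from 1 µg of total RNA with an Illumina preparation kit. The labels do not state whether the libraries or the counting kept the strand of the transcript, so reads of a gene and of an overlapping antisense gene cannot be told apart. Per the submitters' processing notes, STAR 2.5, HTSeq 0.6.1 and DESeq2 (version given as 2) were used with mouse genome build mm10. The notes give no settings, no annotation release and no role for each tool.

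The deposited table of all genes holds FPKM (fragments per kilobase of gene length, scaled by the library's counted reads) for 35275 Ensembl genes, of which 12216 were at 0 in all 10 libraries. A second deposited table lists 908 genes with the authors' adjusted p-value below 0.05 (highest 0.0497), 608 higher and 300 lower in LPS glands. For these genes that table gives whole read counts, which per the file headers are raw counts per gene. It also gives normalized values per library, a signal that the authors made by dividing each count by 1 size factor per library. Its log2 fold changes, LPS over PBS, are the authors' values per the file headers. They were smaller than the log2 ratio of the mean normalized values of the same genes (median ratio 0.871), so they are not on the same scale as the changes computed here. The FPKM of the listed genes were the same in both deposited tables, with a largest relative difference of 2.9e-08.

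For the 908 listed genes, FPKM equalled, up to the constant of the unit, the count divided by the gene length and by 1 whole number of reads per library. That number was 15734303 to 18869545 reads and served as the depth. Gene lengths, and with them whole reads, were then found for 23055 of the 23059 genes above 0, within a tolerance of 0.002 reads, and the recovered reads made up at least 99.98% of each library's depth. Lengths found by this search equalled the listed ones for 906 of 908 genes. A gene of 1 kb with 1 read had an FPKM of 0.053 to 0.0636. PCR copies cannot be told from independent molecules, so this depth limits counting error only. Gene symbols came from a table of Ensembl names for 34470 genes and from the authors' table for 23, and 782 genes had no symbol. Coordinates are those of the authors' table.

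The design and the alternatives were fixed before the data were examined: the test, the filter, the gene lists and the rule for naming genes. Genes with FPKM of at least 1 in at least 5 of the 10 libraries were tested with limma 3.58.1 (linear model and moderated test with an intensity trend, two-sided, in R 4.3.3) on log2(FPKM + 1), and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. The LPS and PBS groups were the only term of the model. Fold changes on the log2(FPKM + 1) scale understate the change of genes with low FPKM. The 33 gene lists (pathways of milk synthesis and inflammation, and markers of the cell types a gland could hold) were tested with limma's camera, which asks whether a list moved against the other tested genes. A preset correlation between genes of 0.01 was used, with adjustment over the 33 lists; 605 of 609 list entries were in the table and 473 were tested. The percent of summed FPKM in milk protein genes was compared by a two-sided exact permutation test over all 252 splits of the 10 libraries. The authors' fold changes and those computed here were compared by a correlation across genes, without a test. The plan allowed for raw counts per library; since counts were deposited for the listed genes only, the FPKM test stayed the one reported. Tests of edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads were added as alternatives.

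Named genes followed this rule. The 10 rises and 10 falls of largest log2 change were taken among called genes whose groups did not overlap and whose mean FPKM was at least 5, leaving out predicted genes, pseudogenes and immunoglobulin segments. In each list up to 4 called members of largest change were taken, or, where none was called, the 2 of highest mean FPKM. A set of 22 genes of endotoxin sensing, inflammation and milk was always included, of which Il6 and Ptgs2 did not pass the filter.

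The alternatives were other pseudocounts (0.1 and 5), other filters (none, or a mean FPKM of at least 5), and other scalings (median-of-ratios, quantile, or FPKM rescaled to the sum outside milk proteins). Further ones were a replicate block, other variance options, library weights, leaving out each library in turn, an estimated correlation in camera, and fry, limma's rotation test of a list by itself. A covariate for B and T cell marker transcripts, and fits without the libraries richest in them, were added after the values were seen.

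The procedures were tested on simulated data for LPS against PBS, with 200 of 11414 genes changed by known amounts. The limma test recovered 24% of genes changed by a log2 of 0.5, 76% at 1, 96% at 2 and 100% at 4, and called 3 unchanged genes. The edgeR test recovered 32, 78, 98 and 100% with 7 unchanged genes called, and DESeq2 recovered 50, 90, 96 and 100% with 25. With no change simulated, limma called 0 genes, edgeR 1 gene and camera 0 lists. The simulated genes varied independently of each other, so the last count does not show how camera acts on correlated genes. Calculations of recovered reads and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.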

Results

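Mammary glands of lactating BALB/c mice, an inbred strain, were compared after injection through the teat canal of LPS, the endotoxin of Gram-negative bacteria, or of PBS as the control. Per the labels, 1 side of the 4th gland pair received 50 µL of LPS at 0.4 mg/mL and the other side PBS on day 3 of lactation, and glands were collected 12 h later. RNA of 5 LPS and 5 PBS glands was sequenced. The labels give n = 9 without stating which animals the 10 libraries came from, and do not state that an LPS and a PBS library of the same number came from the same mouse, so p-values measure the spread between these glands. No gland without an injection was sequenced, and per the labels a PBS gland lay in the same animal as an LPS gland. Depth was 15734303 to 18869545 counted reads per library, and the 10 most abundant genes took 47.7 to 58.6% of summed FPKM. FPKM values below are means ± SD with n = 5 per group, and log2 changes are LPS minus PBS on log2(FPKM + 1) with their SE where given.

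The comparison of LPS with PBS glands asked which transcripts of the lactating gland changed 12 h after endotoxin reached it. Of 11414 genes tested, 300 rose and 69 fell in LPS glands, and 87 of the rises and 11 of the falls were at least 2-fold. Among the rises were both calprotectin genes and, of the lists described below, 21 of 36 tested interferon response genes, 8 of 18 neutrophil markers, 3 of 9 cytokines and 10 of 26 chemokines. Among the falls were 5 of 27 milk fat genes and the osteopontin gene. S100a9 and S100a8 encode the subunits of calprotectin, a metal-binding protein abundant in neutrophils and also made by epithelia. S100a9 rose from 182 ± 135 to 3866 ± 889 FPKM (21.3-fold), and S100a8 from 873 ± 355 to 7386 ± 2044 FPKM (8.46-fold).

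S100a9 (ENSMUSG00000056071) lies on chromosome 3 from 90692632 to 90695721 on the minus strand of build mm10, close to S100a8 (ENSMUSG00000056054), from 90669071 to 90670034 on the plus strand, and both are protein-coding genes. The log2 change of S100a9 was 4.63 ± 0.37 and that of S100a8 3.11 ± 0.26, both with a limma adjusted p of 9.35e-05. Klk10, a secreted serine peptidase of the kallikrein family (ENSMUSG00000030693, chromosome 7, 43781054 to 43785410, plus strand), rose from 1.88 ± 0.478 to 40.3 ± 17.7 FPKM (log2 change 3.75 ± 0.24, adjusted p = 1.69e-05). Stfa3, a stefin A cysteine protease inhibitor, rose from 1.36 ± 0.900 to 35.97 ± 14.5 FPKM (log2 change 3.96), but the stefin A genes are near-identical copies among which reads could be split, so the value of this copy is uncertain. Ptx3, a soluble pattern recognition protein, rose from 0.924 ± 0.847 to 11.6 ± 10.4 FPKM, and Il1rn, the antagonist of the interleukin-1 receptor, from 2.56 ± 0.642 to 15.95 ± 9.70 FPKM. Slfn4, a Schlafen family gene of myeloid cells (ENSMUSG00000000204, chromosome 11, 83175186 to 83190221, plus strand), rose from 7.09 ± 1.64 to 36.6 ± 20.9 FPKM. Ms4a6d, a membrane protein gene of myeloid cells, rose from 51.8 ± 17.6 to 237.2 ± 74.4 FPKM. Plekhs1 and the serine peptidase gene Prss12 completed the 10 largest rises, with log2 changes of 2.23 and 2.05.

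Among the falls, Fabp3, which encodes the fatty acid binding protein of the lactating gland (ENSMUSG00000028773, chromosome 4, 130308595 to 130315463, plus strand), went from 996 ± 528 to 252.7 ± 76.9 FPKM (log2 change -1.86 ± 0.34, adjusted p = 0.0156). Reads of Fabp3 could be shared with its pseudogene copy. Olah, the thioesterase that ends fatty acid chains at medium length for milk fat (ENSMUSG00000026645, chromosome 2, 3341982 to 3366591, minus strand), went from 187.2 ± 17.1 to 79.6 ± 23.1 FPKM (log2 change -1.28 ± 0.20, adjusted p = 0.00715). Spp1, which encodes osteopontin, a phosphoprotein secreted into milk, went from 6092 ± 1328 to 2551 ± 793 FPKM (log2 change -1.28). Gldc, of the glycine cleavage system, had a log2 change of -1.55, and Gnmt, the glycine N-methyltransferase, one of -1.01. Cidea, a lipid droplet protein gene that acts in milk lipid secretion, went from 444.1 ± 59.5 to 234.7 ± 47.5 FPKM, and Lao1, the L-amino acid oxidase of mouse milk, from 1093 ± 90.3 to 604.2 ± 130.0 FPKM. Rogdi, the complement gene C4b and the sodium-proton exchanger gene Slc9a4 had log2 changes of -1.01, -0.99 and -0.73.

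Of the tested genes, 403 had every LPS library above every PBS library and 139 the reverse, which is 4.75% of genes where chance gives 0.794%, and 306 of the 369 called genes were separated in this way. The rises made up 81.3% of the calls, but this share depended on scaling: it was 68.8% with median-of-ratios scaling (254 rises, 115 falls), 61.6% with quantile normalization (233 and 145) and 19.9% with FPKM rescaled to the sum outside milk proteins (134 and 538). The last of these moved the median log2 change of all tested genes from 0.05 to -0.15. On recovered reads edgeR called 305 rises and 132 falls, and DESeq2 546 and 300. The counts also changed when single libraries were left out: 123 genes rose and 27 fell without LPS replicate 2, 164 and 38 without LPS replicate 3, 129 and 31 without PBS replicate 1, and 121 and 29 without PBS replicate 4. Without PBS replicate 5 the number of rises was 178, and without LPS replicate 5 the number of falls was 40. The counts were higher without LPS replicate 1, at 429 and 88. Leaving out a library also leaves fewer glands to test, so a lower count need not come from that library.

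B and T cell transcripts differed between glands of the same group. Cd79a, a subunit of the B cell receptor, was at 12.7 FPKM in PBS replicate 2, 6.41 in PBS replicate 4, 3.65 in LPS replicate 3 and 1.40 in LPS replicate 2, and at 0 to 0.255 FPKM in the other libraries (named after its values were seen). With a score of B and T cell markers as a covariate 651 genes rose and 106 fell. Without the 3 libraries of the highest score 28 genes rose and 7 fell, and without the 4 highest 8 rose and 0 fell in the limma test (829 and 240 at an unadjusted p below 0.05; edgeR called 11 and 2). Over all 100 ways of leaving out 2 libraries of each group, limma called a median of 30.5 genes, between 2 and 802.

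Of the 56 called genes named here, 34 kept the call whichever library was left out. The other 22 lost it without at least 1 library, most often without PBS replicate 4 (22 genes), LPS replicate 2 (20), PBS replicate 1 (18), LPS replicate 3 (14) or PBS replicate 5 (11). Calls lost without 1 to 4 of the 10 libraries, with the highest limma adjusted p, were those of Rogdi (0.0632), Cd36 (0.0584), Lbp (0.0557), Ccl3 (0.0633), Rsad2 (0.0567), Nos2 (0.0593), Mlkl (0.066), Mmp3 (0.0579), F11r (0.0735), H2-D1 (0.0567) and Krt5 (0.0519). Calls lost without 5 or more were those of C4b (0.122), Slc9a4 (0.104), Irak3 (0.138), Rel (0.0654), Socs3 (0.086), Orm3 (0.0808), Gch1 (0.126), Osmr (0.074), Psme2 (0.11), Kit (0.0696) and Krt8 (0.121).

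**Figure D1:**
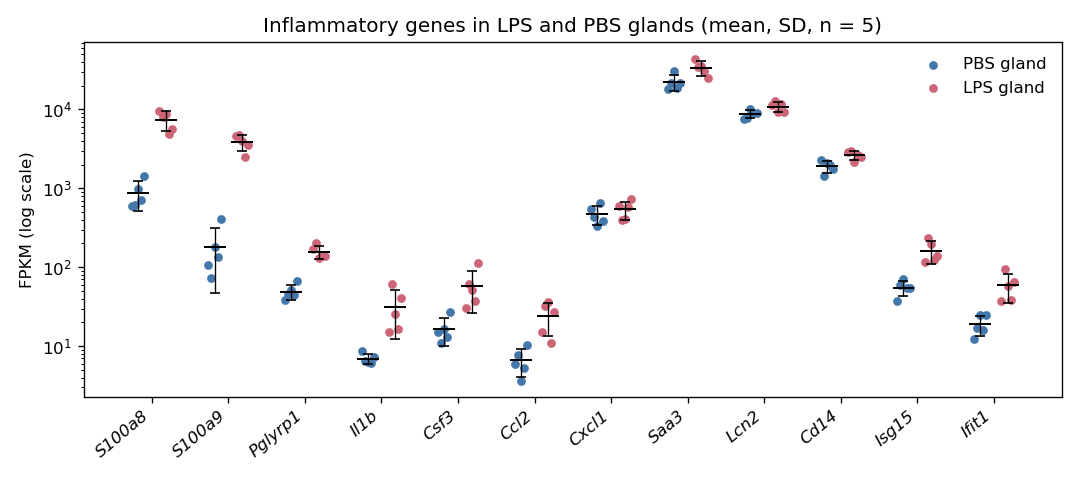
FPKM (log axis) of 12 inflammatory genes in the 5 PBS (blue) and 5 LPS (red) glands. Points are glands, and black bars the mean and SD. S100a9 lies at 182 ± 135 FPKM in PBS and 3866 ± 889 FPKM in LPS glands, while Cxcl1, Saa3, Lcn2 and Cd14 overlap between the groups.

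The comparison of gene lists asked which of 33 pathways and cell types, chosen before the data were examined, moved against the other tested genes. By camera 11 lists were higher and 3 lower in LPS glands, led by the interferon response and neutrophil markers. With a correlation estimated from these libraries 0 lists passed in either direction, although 3 were higher and 2 lower at an unadjusted p below 0.05, and fry called 12 higher and 1 lower. Of 100 splits of the 10 libraries into 5 and 5, the real one included, 18 called at least as many lists, so for the number of lists called chance is not excluded. In the paragraphs that follow, counts of members over all genes tested come first, then those adjusted over the list alone.

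The interferon response list (genes induced by type I and II interferons) had 21 of 36 tested genes higher and 0 lower, and 31 and 0 adjusted over the list alone. Its median log2 change was 0.95 (camera adjusted p = 9.27e-25; adjusted p = 0.223 with an estimated correlation). Oas3, a sensor of double-stranded RNA, rose from 1.95 ± 0.789 to 10.02 ± 4.34 FPKM, Rsad2, which encodes the antiviral protein viperin, from 17.97 ± 8.70 to 56.7 ± 25.1 FPKM, and Ifit1, which binds foreign RNA ends, from 18.9 ± 5.44 to 58.9 ± 23.4 FPKM. Ifit3b rose from 12.6 ± 3.09 to 40.3 ± 15.2 FPKM, a value made uncertain by its near-identical copy Ifit3. The MHC class I pathway, which presents peptides to CD8 T cells, had 2 of 15 genes higher and 0 lower, and 12 and 0 adjusted over the list alone. The list's median log2 change was 0.54, with a camera adjusted p of 3.7e-07 (adjusted p = 0.333 with an estimated correlation). The class I heavy chain gene H2-D1, 1 of a family of similar genes, rose from 217.3 ± 33.4 to 375.6 ± 73.8 FPKM, and Psme2, of the proteasome activator, from 93.3 ± 13.9 to 135.9 ± 19.6 FPKM.

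The cytokine list had 3 of 9 tested genes higher and 0 lower, and 7 and 0 adjusted over the list alone. Its genes had a median log2 change of 0.86, with a camera adjusted p of 8.06e-06 (adjusted p = 0.175 with an estimated correlation). Besides Il1rn, Il1b, the gene of interleukin-1 beta, rose from 6.97 ± 1.10 to 31.8 ± 19.4 FPKM and Csf3, the granulocyte growth factor G-CSF, from 16.5 ± 6.36 to 58.5 ± 32.4 FPKM. Tnf was at 8.08 ± 5.10 and 15.6 ± 8.73 FPKM (adjusted p = 0.260). Il6 did not pass the filter, with means of 0.134 and 2.78 FPKM. The chemokine list had 10 of 26 tested genes higher and 0 lower, and 11 and 1 adjusted over the list alone. At a median log2 change of 0.48, the list had a camera adjusted p of 0.000278 (adjusted p = 0.351 with an estimated correlation). Cxcl5 and Cxcl3, ligands of the neutrophil receptor CXCR2, rose with log2 changes of 2.43 and 1.86, and Ccl2, which attracts monocytes, from 6.64 ± 2.61 to 24.3 ± 10.8 FPKM. Ccl3, a macrophage inflammatory protein, had a log2 change of 1.63. Cxcl1 and Cxcl2, also CXCR2 ligands, were already at 470.3 ± 127 and 96.2 ± 27.4 FPKM in PBS glands and were at 539.4 ± 138 and 135.3 ± 47.4 FPKM in LPS glands (adjusted p = 0.710 and 0.354).

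The list of NF-kB feedback genes, targets and inhibitors of this inflammatory transcription factor, had 4 of 20 genes higher and 0 lower, and 7 and 0 adjusted over the list alone. The list's median log2 change was 0.30, with a camera adjusted p of 4.36e-05 (adjusted p = 0.342 with an estimated correlation). Tnfaip2 rose from 4.39 ± 1.60 to 16.8 ± 6.89 FPKM, Tnip3 from 4.79 ± 0.243 to 10.8 ± 1.505 FPKM, Rel, a subunit of NF-kB, from 2.17 ± 0.524 to 4.05 ± 0.781 FPKM and Socs3, an inhibitor of cytokine signalling, from 15.9 ± 2.44 to 24.7 ± 4.73 FPKM. Nfkbia, the gene of the inhibitor IkB alpha, was at 205.2 ± 26.3 and 245.6 ± 11.4 FPKM (adjusted p = 0.179). The list of inflammasome and lytic cell death genes had 2 of 9 genes higher and 0 lower, and 7 and 0 adjusted over the list alone. Its genes had a median log2 change of 0.56, with a camera adjusted p of 2.72e-05 (adjusted p = 0.317 with an estimated correlation). Its called members were Il1b and Mlkl, the effector of necroptosis, which rose from 11.1 ± 3.35 to 23.2 ± 6.31 FPKM.

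The list of endotoxin sensing and Toll-like receptor signalling had 1 of 22 genes higher and 1 lower, the same numbers adjusted over the list alone, and no camera call (median log2 change 0.09, adjusted p = 0.981). Irak3, an inhibitor of the pathway, rose from 7.10 ± 0.741 to 10.4 ± 1.81 FPKM, and Lbp, which encodes the LPS binding protein, went from 242.4 ± 18.3 to 159.2 ± 27.2 FPKM (log2 change -0.62 ± 0.12). Tlr4, the LPS receptor, was at 13.9 ± 2.28 and 14.8 ± 2.10 FPKM (adjusted p = 0.821), and its co-receptor gene Cd14 at 1907 ± 330 and 2626 ± 328 FPKM (adjusted p = 0.112).

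The list of acute phase and antimicrobial proteins had 5 of 27 genes higher and 4 lower, and 11 and 5 adjusted over the list alone. At a median log2 change of 0.44, the list had a camera adjusted p of 0.0325 (adjusted p = 0.420 with an estimated correlation). Its rises included S100a9, S100a8 and Ptx3. Orm3, an orosomucoid whose copies Orm1 and Orm2 are nearly identical, went from 15.2 ± 8.36 to 3.36 ± 2.05 FPKM, an uncertain value. Saa3, a serum amyloid A made in the gland, was at 22050 ± 4871 and 33890 ± 7126 FPKM (adjusted p = 0.155), the iron-withholding proteins lipocalin 2 (Lcn2) at 8718 ± 1015 and 10850 ± 1469 FPKM (adjusted p = 0.338) and lactoferrin (Ltf) at 2521 ± 295 and 3583 ± 731 FPKM (adjusted p = 0.110). Saa3 and Ltf, but not Lcn2, were among the 11 genes higher adjusted over the list alone. On recovered reads DESeq2 called Saa3 and Ltf (adjusted p = 0.0165 and 0.0428), and edgeR did not (0.163 and 0.213). The camera call of this list ended without LPS replicate 1 (adjusted p = 0.0915), without PBS replicate 2 (0.28), and with the filter on a mean FPKM of 5 (0.147), library weights (0.0997) or the B and T cell covariate (0.417). It also ended with the replicate number as a block (0.234), and without the 3 and without the 4 libraries of the highest B and T cell score (0.203 and 0.116).

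Neutrophil markers had 8 of 18 tested genes higher and 0 lower, and 16 and 0 adjusted over the list alone. The list's median log2 change was 1.06, with a camera adjusted p of 1.34e-13 (adjusted p = 0.173 with an estimated correlation). S100a9, S100a8, Slfn4 and Stfa2l1, another stefin A copy and therefore uncertain, were the largest changes among its tested genes, and the first 2 are also members of the acute phase list. Other markers were highest in 2 of the LPS glands: Csf3r, the G-CSF receptor gene, was at 15.6 and 15.3 FPKM in LPS replicates 2 and 5 and at 3.93 to 8.47 FPKM in the other LPS glands (2.24 to 3.78 in PBS glands), and Cxcr2 at 5.77 and 6.24 FPKM against 1.67 to 1.94 FPKM (0.291 to 1.11 in PBS glands). Monocyte and macrophage markers had 0 of 13 genes called, and 1 higher and 1 lower adjusted over the list alone (median log2 change -0.21, camera adjusted p = 0.0789). Lyz2, a lysozyme of macrophages and neutrophils, was at 133.6 ± 73.7 and 83.4 ± 26.8 FPKM, and C1qa, a complement gene of macrophages, at 29.9 ± 12.2 and 19.6 ± 6.21 FPKM. B and plasma cell markers were lower as a list with 0 of 5 tested genes called, also over the list alone (median log2 change -0.79, camera adjusted p = 0.012; adjusted p = 0.223 with an estimated correlation). The genes Ighm and Igha of the IgM and IgA heavy chains were at 50.6 ± 55.0 and 30.2 ± 25.6 FPKM in PBS and at 11.7 ± 20.2 and 29.0 ± 34.3 FPKM in LPS glands. Ighm was at 93.8 and 123.5 FPKM in PBS replicates 2 and 4, and at 1.515 to 28.4 FPKM in the other PBS glands. With the B and T cell covariate the list was still called (camera adjusted p = 0.0101). The B cell list call ended with median-of-ratios scaling (adjusted p = 0.0708), quantile normalization (0.088), rescaling outside milk proteins (0.342) and fry (0.129).

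T and NK cell markers had 2 of 21 members tested, neither called (camera adjusted p = 0.870), with Gzma, a granzyme, at 5.35 ± 1.08 and 6.79 ± 4.06 FPKM and Nkg7 at 1.52 ± 1.60 and 1.18 ± 1.04 FPKM. With no filter the list was lower (median log2 change -0.36, camera adjusted p = 0.0036). Of the members below the filter, the T cell receptor complex genes Cd3e and Cd3g had means of 2.26 and 2.62 FPKM in PBS and 0.767 and 0.533 FPKM in LPS glands, and Cd3e was at 7.10 FPKM in PBS replicate 2 and 3.63 in PBS replicate 4. The MHC class II pathway had 0 of 5 genes called (median log2 change -0.29, camera adjusted p = 0.0531), with the invariant chain gene Cd74 at 99.6 ± 52.3 and 76.1 ± 19.8 FPKM and H2-Eb1 at 20.9 ± 11.8 and 15.9 ± 4.93 FPKM. Leukocyte adhesion and homing had 0 of 11 genes called (camera adjusted p = 0.509), with the adhesion molecule gene Icam1 at 12.2 ± 4.24 and 22.6 ± 10.2 FPKM and Glg1 at 13.2 ± 1.08 and 12.7 ± 1.78 FPKM. Complement had 0 of 13 genes higher and 1 lower, C4b, which went from 63.0 ± 22.4 to 31.4 ± 10.9 FPKM (camera adjusted p = 0.111). In these 4 lists the counts adjusted over the list alone were the same.

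Milk protein genes were lower as a list, with 0 of 15 genes higher and 1 lower, Spp1, and 0 and 4 adjusted over the list alone. Its genes had a median log2 change of -0.26, with a camera adjusted p of 4.79e-06 (adjusted p = 0.173 with an estimated correlation). The 4 genes lower adjusted over the list alone were Spp1, Trf, Csn3 and Csn2. Single casein and whey genes did not pass the test over all genes: Csn2 (beta-casein) was at 56690 ± 7723 and 37160 ± 6647 FPKM (adjusted p = 0.134), Wap (whey acidic protein) at 70890 ± 8920 and 52840 ± 11250 FPKM (0.351) and Lalba (alpha-lactalbumin, needed for lactose) at 4675 ± 762 and 3681 ± 504 FPKM (0.279). Csn3 (kappa-casein) was at 10860 ± 1283 and 7915 ± 1006 FPKM (0.132). On recovered reads DESeq2 called Csn2 (adjusted p = 0.00309) but not Wap or Lalba, and edgeR did not call Csn2 (0.153). Csn1s1 (alpha-S1-casein) was at 50620 ± 7515 and 51040 ± 8555 FPKM (log2 change 0.01 ± 0.21), and Mfge8 and Muc1 also lay above 0, with log2 changes of 0.08 and 0.01. Genes of milk fat synthesis and secretion were lower as a list, with 0 of 27 higher and 5 lower, and 1 and 6 adjusted over the list alone (camera adjusted p = 0.000225; adjusted p = 0.317 with an estimated correlation, and 0.153 by fry). The list's mean log2 change was -0.21 and its median -0.03, a median that was 0.04 with the B and T cell covariate. Besides Fabp3 and Olah, Btn1a1, the butyrophilin of the milk fat globule membrane, went from 215.0 ± 19.3 to 130.8 ± 22.9 FPKM and the fatty acid transporter gene Cd36 from 187.6 ± 26.3 to 115.5 ± 22.7 FPKM. Fasn, the fatty acid synthase, was at 199.5 ± 63.0 and 189.2 ± 52.2 FPKM (adjusted p = 0.938).

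Cholesterol synthesis genes were higher as a list with 0 of 21 called, and 10 higher and 0 lower adjusted over the list alone. At a median log2 change of 0.50, the list had a camera adjusted p of 1.61e-05 (adjusted p = 0.444 with an estimated correlation, and 0.129 by fry). Fdps, the farnesyl diphosphate synthase, was at 32.9 ± 9.43 and 48.8 ± 17.8 FPKM and Sc5d, a sterol desaturase, at 21.6 ± 2.38 and 30.8 ± 6.58 FPKM. The list of lactose synthesis and milk solute transport had 1 of 18 genes higher and 1 lower, and 1 and 2 adjusted over the list alone (camera adjusted p = 0.226). The zinc importer gene Slc39a4 rose from 23.1 ± 6.40 to 63.7 ± 16.1 FPKM, and Atp2b2, the calcium pump that loads milk, went from 2.70 ± 0.831 to 0.792 ± 0.378 FPKM. Lactogenic signalling had 0 of 12 genes called, and 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.732), with the alveolar transcription factor gene Elf5 at 208.3 ± 18.4 and 198.8 ± 27.4 FPKM and the kinase gene Akt1 at 59.5 ± 4.34 and 59.5 ± 3.21 FPKM.

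**Figure D2:**
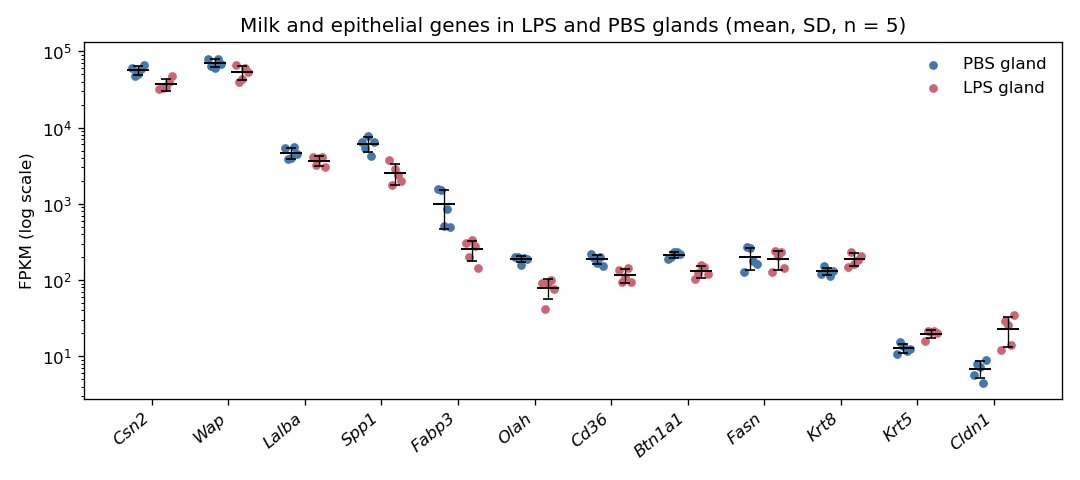
FPKM (log axis) of 12 milk and epithelial genes in the 5 PBS (blue) and 5 LPS (red) glands. Points are glands, and black bars the mean and SD. Fabp3 lies at 996 ± 528 and 252.7 ± 76.9 FPKM in PBS and LPS glands, and Csn2, Wap, Lalba and Fasn overlap between the groups.

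Luminal epithelial markers were higher as a list, with 2 of 15 genes higher and 0 lower, and 6 and 0 adjusted over the list alone. The list's median log2 change was 0.25, with a camera adjusted p of 0.00718 (adjusted p = 0.317 with an estimated correlation). The keratin gene Krt8 rose from 129.5 ± 14.2 to 188.4 ± 34.6 FPKM and the receptor tyrosine kinase gene Kit from 6.61 ± 1.41 to 10.6 ± 1.48 FPKM. Myoepithelial markers were higher as a list, with 1 of 11 genes higher and 0 lower, and 5 and 0 adjusted over the list alone. Its genes had a median log2 change of 0.23, with a camera adjusted p of 0.00111 (adjusted p = 0.388 with an estimated correlation). The basal keratin gene Krt5 rose from 12.8 ± 1.77 to 19.8 ± 2.33 FPKM. With FPKM rescaled outside milk proteins the medians of the luminal and myoepithelial lists were 0.01 and 0.00. The median of all tested genes was -0.15 with that scaling, and camera still called both lists higher (adjusted p = 0.0159 and 0.00369). The luminal call ended without LPS replicate 5 (adjusted p = 0.0642), without PBS replicate 2 (0.0729), with quantile normalization (0.0694), with the B and T cell covariate (0.337) and without the 3 libraries of the highest B and T cell score (0.0566).

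Tight junction genes had 2 of 12 higher and 0 lower, and 5 and 0 adjusted over the list alone (camera adjusted p = 0.0635; 0.0162, higher, by fry). Claudin 1 (Cldn1) rose from 6.86 ± 1.74 to 23.1 ± 9.76 FPKM and F11r, the junctional adhesion molecule A gene, from 50.5 ± 5.44 to 69.2 ± 5.24 FPKM. Involution genes, active when the gland regresses after weaning, had 4 of 16 higher and 0 lower, and 5 and 0 adjusted over the list alone (camera adjusted p = 0.109; 0.00673, higher, by fry). Besides Socs3, Mmp3, the matrix protease stromelysin 1, rose from 29.0 ± 9.42 to 77.6 ± 30.9 FPKM, its inhibitor gene Timp1 from 22.01 ± 1.92 to 37.2 ± 5.01 FPKM and Osmr, the oncostatin M receptor gene, from 10.5 ± 1.51 to 17.1 ± 3.21 FPKM. The list of nitric oxide, superoxide and oxidant defence had 2 of 19 genes higher and 1 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.664). Nos2, the inducible nitric oxide synthase, rose from 1.09 ± 0.391 to 9.48 ± 6.54 FPKM, Gch1, which makes its cofactor, from 18.6 ± 0.794 to 23.3 ± 1.47 FPKM, and Duox1, a dual oxidase, went from 4.26 ± 1.04 to 1.93 ± 0.363 FPKM.

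The remaining lists had 0 called genes, also adjusted over the list alone except for fibroblast markers. The unfolded protein response (18 tested, camera adjusted p = 0.0907) included Xbp1 at 462.2 ± 68.8 and 414.7 ± 68.6 FPKM and the chaperone gene Calr at 359.2 ± 83.6 and 413.3 ± 74.8 FPKM in PBS and LPS glands. The prostaglandin and leukotriene pathway (8 tested, 0.774) included Ptges at 21.2 ± 4.26 and 29.9 ± 6.86 FPKM and Lta4h at 10.4 ± 1.57 and 8.62 ± 1.68 FPKM, and Ptgs2 did not pass the filter, with means of 0.140 and 1.59 FPKM. Cell cycle genes (11 tested, 0.368) included Pcna at 26.1 ± 3.06 and 29.9 ± 5.56 FPKM and Rrm2 at 2.92 ± 0.573 and 3.18 ± 0.512 FPKM. Immediate early genes (9 tested, 0.241) included Ier3 at 53.2 ± 28.3 and 64.9 ± 23.6 FPKM and Btg2 at 42.8 ± 17.5 and 57.2 ± 28.6 FPKM. Endothelial markers (15 tested, 0.352) included Pecam1 at 20.6 ± 3.94 and 20.97 ± 2.02 FPKM and Cldn5 at 19.3 ± 7.18 and 16.7 ± 5.12 FPKM. Adipocyte markers (14 tested, 0.0914) included Fabp4 at 573.0 ± 127 and 552.6 ± 122 FPKM and Cfd at 380.5 ± 135 and 389.4 ± 121 FPKM. Fibroblast markers (13 tested, 0.109) included Col3a1 at 63.0 ± 13.9 and 64.6 ± 21.9 FPKM and Dcn at 51.9 ± 9.96 and 53.4 ± 11.3 FPKM, with 1 gene lower adjusted over the list alone. Skeletal muscle markers (2 tested, 0.865) were Mylpf at 1.40 ± 0.585 and 1.65 ± 0.956 FPKM and Tnni2 at 1.01 ± 0.288 and 1.08 ± 0.678 FPKM.

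Over the 15 lists with 0 called genes, among them the cholesterol and B cell lists that camera called, 22 of 159 tested genes were higher and 7 lower at an unadjusted limma p below 0.05, edgeR called 0 higher and 2 lower, and DESeq2 12 and 3. For 6 lists camera put the direction below the other genes while the median log2 change lay above 0: lactose synthesis and milk solute transport, lactogenic signalling, prostaglandin and leukotriene pathway, T and NK cell markers, endothelial markers (whose mean was -0.02) and skeletal muscle markers. Of the 19 lists that camera did not call, 9 passed without at least 1 library: complement, involution, tight junctions, the unfolded protein response, the MHC class II pathway, immediate early genes, and macrophage, adipocyte and fibroblast markers. The lowest adjusted p-values of these lists were 0.0274, 0.0186, 0.00619, 0.00965, 0.00564, 0.0299, 0.00993, 0.00926 and 0.0225, in that order, reached without LPS replicate 3 for involution and tight junctions, without PBS replicate 2 for the unfolded protein response, without LPS replicate 4 for fibroblast markers and without PBS replicate 5 for the other lists.

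**Figure D3:**
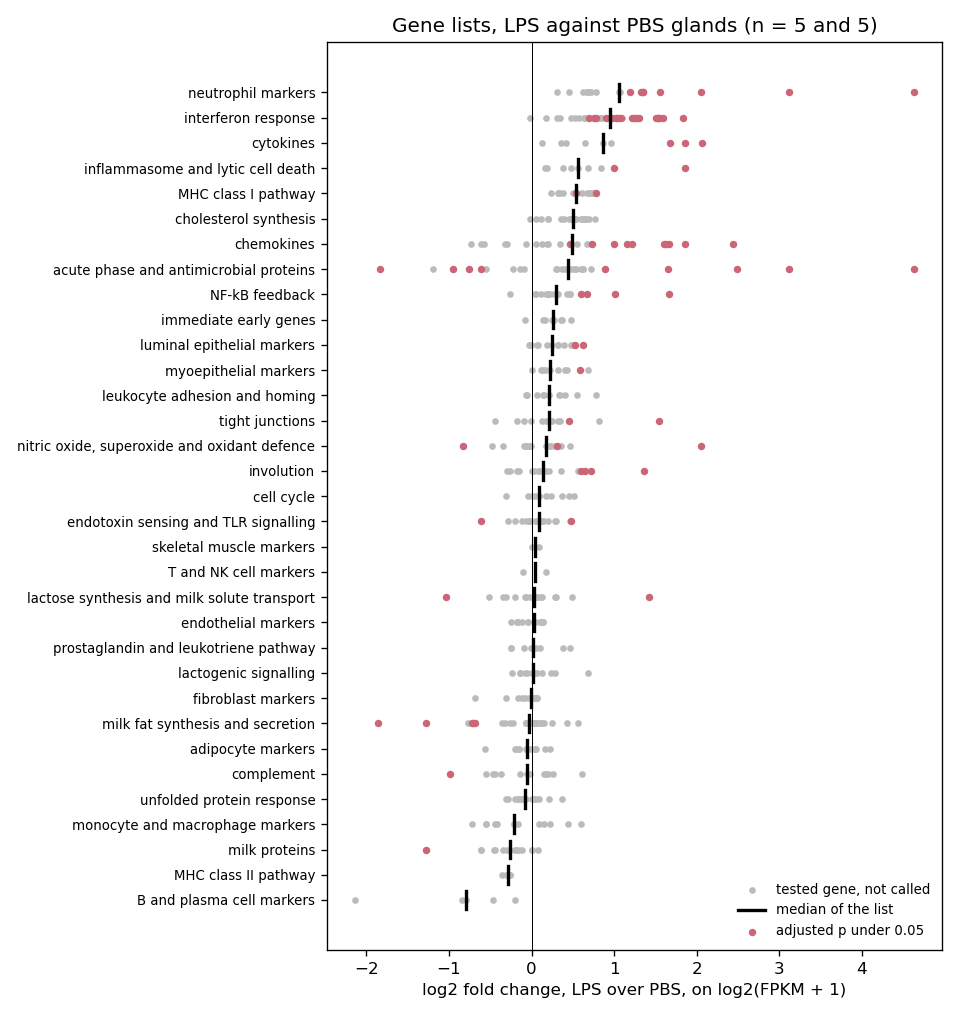
Log2 change, LPS over PBS, of each tested gene of the 33 lists (x axis, on log2(FPKM + 1); y axis, list), with genes of adjusted p under 0.05 in red and the list median as a black bar. The medians run from -0.79 for B and plasma cell markers to 1.06 for neutrophil markers.

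The milk protein share asked how much of summed FPKM came from milk protein genes. FPKM is scaled by counted reads, so a shift in the reads of these genes moves the FPKM of all other genes. Summed FPKM weighs short transcripts more than reads do, so this share does not give the size of that move. Milk protein genes made up 47.0 ± 5.15% of summed FPKM in PBS and 37.6 ± 4.82% in LPS glands (SD, n = 5 per group), and the difference of -9.44 percentage points had a two-sided exact permutation p of 0.0317. The LPS glands ranged from 33.5 to 45.4% and the PBS glands from 40.7 to 52.0%. The share of acute phase and antimicrobial transcripts went the other way, from 13.7 ± 2.63% to 19.7 ± 2.93% (difference 6.02 points, exact permutation p = 0.0159). Of 6 measures of this kind, the acute phase, luminal, lymphoid and mitochondrial ones were added after the data were seen. Adjusted over the 6, the permutation p was 0.0596 for the milk protein share and 0.0477 for the acute phase share. Mitochondrially encoded genes made up 1.89 ± 0.41% in PBS and 2 ± 0.5% in LPS glands (exact permutation p = 0.682). The milk protein share did not pass the threshold without LPS replicate 1, 2 or 3 or PBS replicate 1 or 5, with differences of -9.16, -8.41, -8.55, -8.19 and -8.37 points and an exact permutation p of 0.0556 each.

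The comparison with the authors' table described how far their fold changes and those computed here were alike. Of the 908 genes they listed, 806 passed the filter, and the log2 changes had a Pearson r of 0.945 across these genes, which are not independent replicates, with the same sign for 100% of them. These genes were listed for passing the authors' test on the same libraries. The same sign was therefore nearly fixed beforehand, and r leaves out genes with changes near 0. Of the 369 genes called here, 349 were in their list and 20 were not. S100a8 and S100a9 had log2 changes of 1.88 and 1.59 in the authors' table, against 3.11 and 4.63 here, so both were smaller there and in the reverse order. On recovered reads DESeq2 gave 2.98 and 4.29 and edgeR 2.99 and 4.30, in the order found here. How the authors' fold changes were computed is not stated. Klk10 had one of 3.20 there, Fabp3 one of -1.22 and Olah one of -1.09, against 3.75, -1.86 and -1.28 here, and all 5 genes had adjusted p-values below 0.05 there by the way the table was made.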

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

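Of the tests weighed in this part, those on the B and T cell transcripts and on the falling genes, and the slope test on S100a8 and S100a9, were chosen only after the result was seen. The first test set for the falling genes, written before its result was seen, was the share kept when FPKM is rescaled outside milk proteins. It gave 69 of 69 but was void, because that rescaling itself lowers genes in LPS glands. The first test of the neutrophil markers, a correlation, gave r = -0.047. The 3 correlations over glands in this part had adjusted permutation p-values of 9e-04, 0.00422 and 0.87.

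In 10 of 212 groups of 5 glands (4.7%), 1 gland lay far from the nearest of the others by Dixon's criterion, about the 1 in 20 that chance gives. C4b was at 102.9 FPKM in PBS replicate 3 and at most at 55.8 FPKM in the other PBS glands. Fdps was at 79.7 FPKM in LPS replicate 2, with the next LPS gland at 46.2 FPKM, and Ccl3 at 16.3 FPKM in the same gland, with the next at 5.51 FPKM. Atp2b2 was at 1.45 FPKM in LPS replicate 4, with the next at 0.734 FPKM. Akt1 was at 66.9 FPKM in PBS replicate 2, with the next at 58.8 FPKM, and Stfa2l1 at 1.29 FPKM in that gland, with the next at 0.401 FPKM. Ighm was at 47.5 FPKM in LPS replicate 3, with the next at 7.63 FPKM, and Igha at 89.5 FPKM in LPS replicate 1, with the next at 23.4 FPKM. LPS replicate 1 was also lowest for Pecam1, at 17.5 FPKM against 21.5 FPKM in the next gland, and for Krt5, at 15.7 FPKM against 20.04 FPKM.

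B and T cell marker transcripts differed many-fold between glands of the same group: the B cell gene Ms4a1 was at 5.30 FPKM in PBS replicate 2, 2.05 in PBS replicate 4 and 2.95 in LPS replicate 3, and at 0.968 FPKM or less in the other glands. The LPS and PBS groups held 11% of the variance of the B and T cell marker score, so most of it lay between glands of the same group. That is the pattern itself, so this share is no separate evidence on the treatment. The deviations of the T cell and the B cell scores from their group means went together over the 10 glands (Pearson r = 0.983, permutation p = 3e-04; Spearman rho = 0.988, permutation p = 0.00047; r = 0.967 without the 2 farthest glands). Ccl21a, a chemokine of lymph node stroma, was at 66.9 FPKM in PBS replicate 2, 27.2 in PBS replicate 4 and 4.85 in LPS replicate 3, and at 0.746 FPKM or less elsewhere, and lymph node stroma and traffic genes followed the score with r = 0.977 (permutation p = 0.00281). A candidate explanation is lymphoid tissue, such as the lymph node that lies in this gland pair, in some of the gland pieces, and lymphocytes that gathered in some glands for other reasons stay open, as untested.

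Genes that fell in LPS glands, milk fat genes among them, had a median log2 change of -0.70. FPKM scaling by a sum that a few genes dominate would lower the other genes alike, but the median of all tested genes was 0.048. The tested genes as a whole were thus not lowered, although the falls, chosen as low, lie below that median in any case. With median-of-ratios scaling 62 of the 69 falls were also called. That scaling lowers genes in LPS glands (median of all tested genes -0.009), so this count cannot decide. A smaller share of luminal epithelium as a whole would lower luminal markers, but the luminal marker score was higher in LPS glands by 0.206 (SE 0.048) on the log2 scale. The score holds markers of luminal cells in general, such as Krt8, Kit, Esr1 and Pgr, so it cannot tell the share of secretory cells. The luminal list had a median of 0.01 with FPKM rescaled outside milk proteins, against -0.15 for all tested genes. Camera still called it higher there (adjusted p = 0.0159). Endotoxin could also have changed luminal markers within epithelial cells. Transcript levels per epithelial cell were not measured. A smaller share of secretory cells and a lower level of these transcripts within the epithelium of LPS glands both stay open, as untested.

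S100a8 and S100a9 rose by more, on log2(FPKM + 1), than the other 16 neutrophil markers that passed the filter. Trem1, a member below the filter, had means of 0.155 and 1.66 FPKM in PBS and LPS glands, a larger ratio than that of S100a8. The pseudocount understates the rise of low genes, but with edgeR on recovered reads these 16 markers had a median log2 change of 1.43 (median absolute deviation 0.93), against 2.99 for S100a8 and 4.30 for S100a9, so it does not account for the gap to these 16 as a set. It does account for most of the gap between S100a8 and 1 of them, Stfa2l1, whose log2 change was 1.55 on log2(FPKM + 1) and 2.85 with edgeR. If neutrophils were the only source, the S100a8 and S100a9 levels would follow the other markers among glands of a group, and the slope of these deviations was -0.08 (SE 0.63; Pearson r = -0.047, permutation p = 0.87; Spearman rho = -0.127, permutation p = 0.72; r = -0.087 without the 2 farthest glands). The spread of the slope is too wide, with 10 glands, to tell neutrophil RNA as the only source from an added epithelial source.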

How the results depend on the processing

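The fits with the B and T cell covariate, those without the libraries richest in B and T cell markers and those on recovered reads were chosen only after the data were seen, and the other settings were planned. Of the 300 rises and 69 falls, pseudocounts, a mean FPKM filter and variances without trend or robust moved the counts by less than 1.5 times. Under the settings planned for single genes 0 of 99 named genes were reversed. A change of sign counted as reversed only for a gene called in the fit reported or in the other fit. Sign changes of genes called in neither were not counted. These settings did not include robust variances or library weights, and gave 89 of these genes a value with the mean FPKM filter. Counts of rises and falls were 101 and 25 with no filter (23059 genes tested), 254 and 115 with median-of-ratios scaling, 233 and 145 with quantile normalization, 134 and 538 with FPKM rescaled outside milk proteins, 534 and 122 with library weights, 403 and 139 for groups that did not overlap, 305 and 132 with edgeR, and 546 and 300 with DESeq2, which gave no adjusted p for 445 genes. They were 651 and 106 with the B and T cell covariate (297 and 67 shared with the calls reported), 28 and 7 without the 3 libraries richest in these markers (26 and 6 shared) and 8 and 0 without the 4 richest. Leaving out 1 library gave 121 to 429 rises and 27 to 88 falls. With no filter 30 named genes lost the call, and 25 of the 56 called kept it under each of the settings planned for single genes that gave them a value. The cause of these changes was not tested. Depth limits genes near 1 FPKM.

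Of the 11 lists higher and 3 lower, 0 and 0 passed with an estimated correlation, which widens the error of a list of correlated genes. Lists lower numbered 5 with no filter, 5 with library weights, 5 with the covariate, 1 with fry and 3 to 7 on leaving out 1 library. The number higher stayed within 1.5 times in every other setting. The skeletal muscle list had no gene left with the mean FPKM filter and gave no value there. The difference in milk protein share lay between -8.19 and -11.4 points on leaving out 1 library (exact permutation p 0.0159 to 0.0556), at -9.55 without the 3 libraries richest in B and T cell markers (p = 0.114, exact) and at -7.89 without the 4 richest (p = 0.2, exact; 0.1 is the smallest for 3 against 3). It was -8.82 for caseins, Wap, Lalba and Glycam1 alone and -9.56 without mitochondrially encoded genes, both past the threshold.

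With the replicate number as a block, 962 genes rose and 267 fell (all 369 calls shared), 6 of the 99 named genes gained a call (Tnf, Icam1, Sc5d, Ptges, C1qa and Fdps) and 0 lost one, 7 lists were lower, with complement, the unfolded protein response, the MHC class II pathway and macrophage markers added (adjusted p = 0.0331, 0.0331, 0.0371 and 0.0236), the acute phase list lost its call (adjusted p = 0.234), and edgeR with the block called 772 and 518. The milk protein share, at -9.44 points, had an exact sign-flip permutation p of 0.0625 over the numbered pairs, the smallest that 5 pairs allow. Deviations of same-numbered libraries from their group means had correlations of 0.482, 0.362, 0.0993, 0.103 and 0.494. Not every library correlated best with its own number: LPS replicates 3 and 4 and PBS replicates 2, 3 and 4 did so with another.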

Other observations

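The lists of this part and the genes ranked in PBS glands were chosen only after the values were seen, so no test of these lists is given; the splits of the libraries were planned. Proteasome subunit genes, outside the immunoproteasome subunits of the MHC class I list, moved together: all 32 tested subunits lay above 0 in log2 change (0.13 to 0.75), 11 rose, and the median was 0.40 (0.34 with median-of-ratios scaling). Their estimated correlation was 0.66, so they are not 32 independent genes. Of the S100 family, small calcium-binding proteins, 6 of 10 tested genes rose, S100a8 and S100a9 among them, with a median log2 change of 0.95, from 0.13 to 4.63. Of the stefin A family, cysteine protease inhibitors, all 5 tested genes rose, with a median log2 change of 2.98, from 1.55 to 3.96. These 5 are near-identical copies among which reads could not be assigned with certainty, and their estimated correlation was 0.69, so they are not 5 independent genes.

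PBS glands held abundant transcripts of acute phase and antimicrobial proteins. Among 23059 genes above 0, Saa2 ranked 6, Saa3 7 and Saa1 8 by mean FPKM in PBS glands, at 22850, 22050 and 21440 FPKM, with Lcn2 at rank 12, Orm1 at 13 and Ltf at 22. Saa1 and Saa2 are near-identical copies, so the level of each is uncertain. The lowest PBS gland held 18100 FPKM of Saa3. Cd14 ranked 24, at 1907 FPKM, Clu, a gene of involution, 28, and Cxcl1 72. No gland without an injection was measured, so whether these levels belong to lactation day 3, to the injection, or to LPS in the opposite gland was not tested.

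Other splits of the 10 libraries into 5 and 5 were run, 100 of the 126 that are possible. For genes, 1 of the 100 splits, the real one, gave as many calls (369, against 21 in the highest other). No other split that was run came near the real one, but not all 126 were run. The other splits also mix LPS and PBS glands, which widens the spread within their groups and lowers their calls. For gene lists, 18 of the 100 splits gave as many calls as the real one (14, against 21 in the highest other), so for the number of lists called chance is not excluded.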
